A study of Mus musculus with 46 samples.

How the data were processed

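Livers of control and CCl4-treated mice were profiled on Affymetrix mouse arrays from oligo-dT primed cDNA and biotin-labelled cRNA, per the labels' protocols. The values are log2 expression values that the authors deposited, made with oligo 1.52.0 and RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises probes into probe sets, so small shifts common to most genes are removed. No scan date or batch is given in the sources used here. The 46 arrays were placed in 9 groups by their labels, and 0 per-sample columns were left unused.

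Of 45101 probe sets 64 were controls, 34945 named 1 gene, 932 named several and 9160 had no listed gene, and only those with 1 gene were used for gene results. Symbols were updated through Entrez IDs, which matched for 34754 probe sets. Each of 18193 genes was read from the probe set with the highest mean over all arrays. Genes were tested where it exceeded the median of all values (5.55823) on at least 5 arrays, which left 13239 genes and removed 4954. For 5229 genes another probe set passed that filter as well, and the number of genes with a probe set called in the opposite direction was 42, 120, 192 and 154 at 2 h, 8 h, 1 d and 2 d, 3 at 4 d and 0 later. Genes with near-identical copies read by probe sets ending in _x_at or _s_at are called uncertain.

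All arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) of the group means with lmFit and eBayes and 37 residual degrees of freedom. The 8 times were compared with control, the 7 steps between neighbouring times were tested, and an F-test covered all times. Adjusted p values are from limma with Benjamini-Hochberg adjustment within a contrast, and genes were called under 0.05. The 34 gene lists (at least 3 genes tested) were tested with fry, adjusted over all lists and times, or lists and steps. Fry asks whether a list's genes move on balance 1 way and compares with no other genes, and its mixed test asks for change in either direction. Camera with a preset correlation of 0.01 and with an estimated correlation were the alternatives. Array measures were compared by two-sided exact permutation tests, where the smallest p is 0.00794 for 5 arrays against 5 and 0.00216 for 6 against 5. Plots were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

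The lists covered pericentral and periportal hepatocytes, cytochrome P450 and drug metabolism, bile acids, cholesterol synthesis, fatty acid synthesis and oxidation, immediate early genes, Nrf2 targets, the unfolded protein response, heat shock proteins, p53 targets, the acute phase, cytokines, interferon, S phase, mitosis, ribosome biogenesis, activated and quiescent stellate cells, Kupffer cells, monocyte-derived macrophages, neutrophils, T and NK cells, B cells, endothelium, cholangiocytes, fetal liver, the circadian clock, male-biased and female-biased genes, erythroid cells, exocrine pancreas, and adipose and mesothelial cells. Genes named at each time are the 6 largest rises and 6 largest falls among called genes whose arrays all lay beyond all control arrays (clone names left out), the 4 largest called members of each called list (2 at a step), and a fixed panel. Groups, tests, lists, naming rule and most other settings were chosen before the data were examined. The alternatives were other array scalings, filters, probe set rules, samples in the fit, variance models, array weights, adjustments, fold thresholds, a replicate block and each array left out in turn. Covariates and the fit without arrays 1 and 2 at 1 d were added after seeing the data.

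The tests were run on simulated data with 200 changed genes of 13239. Against control 77.9% to 92.6% of genes changed 1.5-fold, 92.4% to 98.5% at 2-fold and 100% at 4-fold were recovered over the 8 times. For the steps these were 85.3% to 91.2%, 93.9% to 100% and 100%. Of called genes, 3.05% to 7.28% over times and 2.55% to 6.97% over steps were unchanged, against 5% aimed at. Of 2 lists shifted by 0.5 at 2 h both were recovered, with 0 of 270 other list tests called. Whether this holds for correlated genes was not shown.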

Results

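Gene expression was measured in livers of male C57BL/6N mice after a single intraperitoneal injection of carbon tetrachloride (CCl4). CCl4 is a solvent that hepatocytes turn into a toxic radical, mainly through the cytochrome P450 enzyme Cyp2e1 around the central veins. The dose was 1.6 g/kg in olive oil. The 46 Affymetrix arrays form 9 groups, with 5 untreated controls, 5 arrays at each of 2 h, 8 h, 1 d, 2 d, 4 d, 6 d and 8 d after the injection, and 6 arrays at 16 d. The controls are labelled untreated, so the injection and the oil are part of every comparison with control, and the time of day of sampling is not given in the sources used here. The labels number the arrays of a group without saying that each came from its own animal, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. For 5 arrays against 5 the median standard error of a log2 fold change over the 13239 genes tested was 0.0966. Errors after ± are standard errors of log2 fold changes from the limma fit unless an SD is named.

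Arrays of the same group correlated across genes with r from 0.947 (between arrays at 1 d) to 0.993, where genes are not independent replicates. The first and second principal components held 39.5% and 21.4% of the variance. Over the whole time course 11042 genes (83.4%) passed the F-test for any difference from control, and 9635 of these were also called at 1 time or more. The largest change of these genes fell at 1 d for 3281 genes (34.1%), at 8 h for 2585, at 2 d for 2196 and at 2 h for 1089, against 286 at 4 d, 18 at 6 d, 44 at 8 d and 136 at 16 d. The 3 prime minus 5 prime control value of Gapdh, a sign of RNA integrity, was 0.347 ± 0.0646 (SD, n = 5) in controls. It differed by -0.211 to -0.148 from 2 h to 4 d (adjusted p from 0.0317 to 0.0381, exact permutation tests). The same measure of actin was not called at any time (0.254 to 0.524). The interquartile range of all values differed from control by 0.0989 at 1 d, 0.115 at 2 d and -0.0752 at 16 d (adjusted p = 0.0212 each, same tests).

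**Figure D1:**
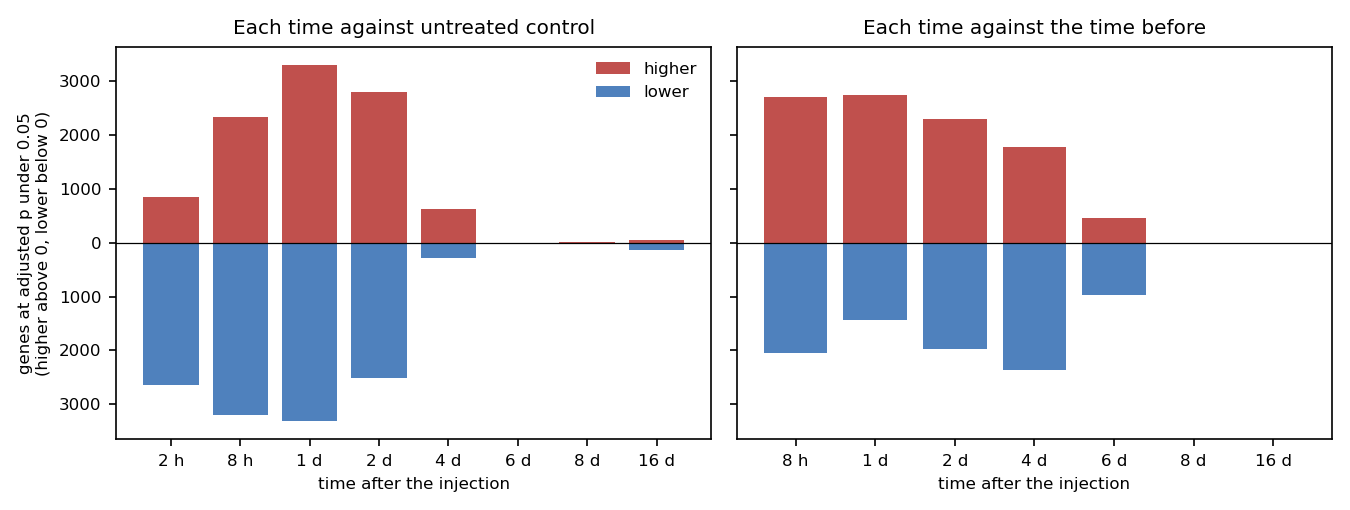
Bars give the number of genes higher and lower at an adjusted p under 0.05, at each time against control and at each step between neighbouring times, out of 13239 genes tested. The counts against control stand at 3305 higher and 3318 lower at 1 d and 3 higher and 0 lower at 6 d.

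At 2 h against control Fos and Jun, which encode subunits of the AP-1 transcription factor, rose 44.6-fold (log2 fold change 5.48 ± 0.38, n = 5 per group) and 31.7-fold (4.99 ± 0.40). Atf3, a stress-induced transcription factor, rose 32.0-fold (5.00 ± 0.32), and Gadd45a, a gene induced by growth arrest and DNA damage, rose 29.2-fold (4.87 ± 0.39). The inducible Hsp70 chaperones Hspa1a and Hspa1b rose 66.5-fold (6.06 ± 0.48) and 24.8-fold (4.63 ± 0.55). Among the genes that fell, G0s2, an inhibitor of triglyceride breakdown, fell 3.57-fold (-1.84 ± 0.37) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 3.09-fold (-1.63 ± 0.51, adjusted p = 0.0147, and 0.0528 without control array 3, -1.33 and 0.13 with the Gapdh value and -1.05 and 0.175 with the Cre spike-in as a covariate). In each of these genes all 5 arrays at 2 h lay beyond all 5 control arrays.

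Of 20 immediate early genes tested at 2 h, 19 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 4.47e-15 with fry and 0.000918 with an estimated correlation). They included Egr1, a zinc finger transcription factor, at 19.2-fold (4.26 ± 0.44). Of 14 heat shock protein genes 13 rose, as did 13 adjusted over the list alone, among them Dnajb1 at 14.2-fold (3.82 ± 0.27) and Hspb1 at 5.28-fold (2.40 ± 0.43). That list gave an adjusted p of 5.88e-10 with fry and 0.0361 with an estimated correlation. The unfolded protein response list moved both ways, with 8 of 20 genes higher and 4 lower, the same adjusted over the list alone. Chac1, which degrades glutathione, rose 11.2-fold (3.48 ± 0.33), and Ddit3, the stress transcription factor CHOP, rose 4.90-fold (2.29 ± 0.22). The list's test was upward (adjusted p = 0.000838, and adjusted p = 0.36 with an estimated correlation), as was its mean of 0.49, whereas its median was -0.01. Likewise 6 of 17 p53 target genes rose and 5 fell (7 and 7 adjusted over the list alone), with a median of -0.15, a mean of 0.57 and an upward test (adjusted p = 0.000173, and adjusted p = 0.384 with an estimated correlation). The p53 targets that rose most were Btg2, which is also an immediate early gene, at 16.6-fold (4.06 ± 0.27) and Trp53inp1 at 9.13-fold (3.19 ± 0.28), and Cdkn1a, the cell cycle inhibitor p21, rose 3.08-fold (1.62 ± 0.30) on average, with log2 values of 8.57 to 9.26 on arrays 1 to 3, 6.97 and 6.79 on arrays 4 and 5 and 6.34 to 6.47 in controls.

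Markers of sinusoidal endothelial cells were lower at 2 h, with 9 of 19 down and 1 up, the same adjusted over the list alone (adjusted p = 0.000177, and adjusted p = 0.528 with an estimated correlation). Tek and Kdr, receptors of angiopoietin and of vascular endothelial growth factor, differed by -0.53 ± 0.10 and -0.42 ± 0.07. Of the fixed panel, Hmox1, the haem oxygenase of the oxidative stress response, rose 2.57-fold (1.36 ± 0.27). Cyp2e1 (-0.01 ± 0.27, adjusted p = 0.982), Glul, the pericentral glutamine synthetase (0.17 ± 0.18, 0.528), and the acute phase genes Saa1 (1.80 ± 0.70, 0.051) and Lcn2 (1.95 ± 0.80, 0.0662) were not called. Saa1 passed without array 1 at 2 h (0.0477) or control array 1 (0.0139) and with quantile normalization (0.0474) or cyclic loess (0.038), and Lcn2 without array 2 at 2 h (0.0431).

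In total 3486 of 13239 genes were called at 2 h, 848 higher and 2638 lower, and 194 of them by at least 2-fold, 148 higher and 46 lower. The split of calls moved to 1153 higher and 1899 lower with quantile normalization and to 1238 and 1362 with cyclic loess. The fry test called 9 of 34 lists, 6 up and 3 down. The others included the exocrine pancreas list, up with Cela3b at 0.40 ± 0.08 (-0.01 with its other probe set) and 1 of 6 genes called (adjusted p = 0.00321, and adjusted p = 0.342 with an estimated correlation; 0.0627 with the mean of all probe sets). The adipose and mesothelial list was up with 1 of 5 genes called. That gene was Krt8, a keratin that hepatocytes also express, at 1.08 ± 0.24 (adjusted p = 0.00367 for the list, and adjusted p = 0.317 with an estimated correlation; 0.237 with no filter). The pericentral list was down with 4 of 15 genes called, Tbx3 by most at -1.20 ± 0.18 (adjusted p = 0.0487, and adjusted p = 0.874 with an estimated correlation). The periportal list was down with 5 of 14, Aldh1b1 by most at -1.22 ± 0.34 (-0.90 and 0.123 for the gene with the Gapdh value as a covariate; 0.0385 for the list, and adjusted p = 0.845 with an estimated correlation). The pericentral call ended without any 1 of the arrays 2, 3, 4 and 5 at 2 h and control arrays 2, 3 and 4 (adjusted p from 0.051 to 0.169). It also ended with quantile normalization (0.116), cyclic loess (0.31), no filter (0.0515), the stricter filter (0.26) and the mean of all probe sets (0.363). The periportal call ended without any 1 of the arrays 1, 3 and 4 at 2 h and control arrays 1, 2, 3 and 5 (0.0529 to 0.0904), with quantile normalization (0.0976), cyclic loess (0.573) and the stricter filter (0.0545).

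At 8 h the largest rises against control included Hspa1a at 37.8-fold (5.24 ± 0.48, n = 5 per group), Psat1, an enzyme of serine synthesis, at 33.9-fold (5.08 ± 0.28) and Srxn1, which repairs oxidised peroxiredoxins, at 30.7-fold (4.94 ± 0.34). The secreted acute phase protein gene Lcn2 rose 31.5-fold (4.98 ± 0.80) on average, with log2 values of 8.06 and 8.07 on arrays 1 and 2, 12.06 to 12.47 on arrays 3 to 5 and 5.61 as the control mean. The metallothionein gene Mt2 rose 23.1-fold (4.53 ± 0.57). Falls were led by Nrep at 14.4-fold (-3.85 ± 0.45), Upp2, a uridine phosphorylase, at 9.76-fold (-3.29 ± 0.53), Slc1a2, a glutamate transporter of pericentral hepatocytes, at 8.71-fold (-3.12 ± 0.29) and Hmgcs1, an enzyme of cholesterol synthesis, at 8.04-fold (-3.01 ± 0.29). All of these genes passed at an adjusted p of 1.93e-06 or below. Over all probe sets of a gene the log2 fold change ran from 0.78 to 4.94 for Srxn1, -3.39 to -0.81 for Upp2 and -3.12 to 0.14 for Slc1a2.

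The unfolded protein response list rose as a whole at 8 h, with 19 of 20 genes up and 19 adjusted over the list alone (adjusted p = 8.66e-17 with fry and 0.00862 with an estimated correlation). Ddit3 rose 14.4-fold (3.85 ± 0.22, and 0.27 with its other probe set) and Creld2, a chaperone of the endoplasmic reticulum, 13.3-fold (3.74 ± 0.33). Heat shock genes stayed above control, with 13 of 14 up and 1 down, also over the list alone (adjusted p = 8.58e-13, and adjusted p = 0.0927 with an estimated correlation), and Hspb1 was 22.1-fold above control (4.47 ± 0.43). Of 22 ribosome biogenesis genes 21 rose, also over the list alone, with Nop58, a small nucleolar RNA-binding protein, at 6.78-fold (2.76 ± 0.25). Its test gave an adjusted p of 1.61e-10, and adjusted p = 0.167 with an estimated correlation. Targets of Nrf2, the regulator of the oxidative stress response, moved unevenly, with 7 of 17 up and 3 down, the same over the list alone (adjusted p = 9.59e-09, and adjusted p = 0.246 with an estimated correlation). Txnrd1, a thioredoxin reductase, rose 5.45-fold (2.45 ± 0.17) and Hmox1 rose 2.70-fold (1.43 ± 0.27). Immediate early genes were up in 10 of 20, also over the list alone, with Atf3 11.7-fold (3.55 ± 0.32) and Myc 7.83-fold (2.97 ± 0.32) above control. Fos was not called (0.43 ± 0.38, adjusted p = 0.397). Their list gave an adjusted p of 4.92e-05, and adjusted p = 0.473 with an estimated correlation.

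Hepatocyte gene lists fell at 8 h. Of 16 cholesterol synthesis genes 14 fell and 0 rose, also over the list alone (adjusted p = 2.24e-06, and adjusted p = 0.501 with an estimated correlation). Of 15 pericentral markers 10 fell, also over the list alone, with Oat, an ornithine aminotransferase, 5.00-fold lower (-2.32 ± 0.25) and Glul 2.14-fold lower (-1.10 ± 0.18). Cyp2e1 was not called (-0.45 ± 0.27, adjusted p = 0.183, but 0.000565 with only both groups in the fit). The pericentral list gave an adjusted p of 2.82e-08, and adjusted p = 0.342 with an estimated correlation. Of 14 periportal markers 9 fell and 1 rose, the same over the list alone (adjusted p = 0.000177, and adjusted p = 0.636 with an estimated correlation). Of 21 cytochrome P450 and drug metabolism genes 14 fell and 1 rose (16 and 1 over the list alone). Their list gave an adjusted p of 3.81e-07, and adjusted p = 0.433 with an estimated correlation. Bile acid genes fell in 9 of 16 and rose in 1, also over the list alone, with Cyp7a1 4.58-fold lower (-2.19 ± 0.51). That list gave an adjusted p of 0.000103, and adjusted p = 0.63 with an estimated correlation. Fatty acid synthesis genes fell in 7 of 16, also over the list alone. In addition 7 of 12 male-biased liver genes fell (8 over the list alone). These lists gave adjusted p = 9.95e-05 (adjusted p = 0.657 with an estimated correlation) and 0.000121 (adjusted p = 0.63 with an estimated correlation).

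Some markers of other liver cells were below control at 8 h. Of 19 sinusoidal endothelial markers 13 fell and 2 rose, also over the list alone (adjusted p = 2.41e-05, and adjusted p = 0.63 with an estimated correlation). Of 12 resident Kupffer cell markers 8 fell and 1 rose, also over the list alone (adjusted p = 0.0133, and adjusted p = 0.869 with an estimated correlation), where Kupffer cells are the macrophages of the liver. Their lectin receptor gene Clec4f differed by -0.45 ± 0.14 (adjusted p = 0.0101, and -0.29 and 0.0791 with the 18S value as a covariate) and the haemoglobin scavenger receptor gene Cd163 by 0.89 ± 0.24. Quiescent stellate cell markers fell in 5 of 12, also over the list alone, with the retinol acyltransferase gene Lrat at -0.90 ± 0.19 (adjusted p = 0.0122, and adjusted p = 0.874 with an estimated correlation; 0.0754 with cyclic loess, 0.0652 with no filter and 0.121 with the stricter filter). Erythroid genes fell in 2 of 4 (adjusted p = 0.00253, and adjusted p = 0.778 with an estimated correlation). The adipose and mesothelial list was up with 2 of 5 genes called, the lipid droplet gene Cidec at 2.79 ± 0.41 and Krt8 at 2.40 ± 0.24 (adjusted p = 4.6e-06, and adjusted p = 0.433 with an estimated correlation; 0.105 with no filter).

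In total 5549 genes were called at 8 h, 2342 higher and 3207 lower, of which 476 and 397 changed by at least 2-fold. Of 34 lists 19 were called, 7 up and 12 down. The acute phase list rose in 9 of 22 genes, also over the list alone, including Saa1 at 9.24-fold (3.21 ± 0.70) and Serpina3n at 4.22-fold (2.08 ± 0.30), with an adjusted p of 0.027, and adjusted p = 0.77 with an estimated correlation. Its call ended without any 1 of the arrays 3, 4 and 5 at 8 h and control arrays 2, 3 and 4 (adjusted p from 0.0545 to 0.086). The fatty acid oxidation and PPAR alpha list was down with 9 of 17 genes lower and 1 higher, also over the list alone (adjusted p = 0.0242, and adjusted p = 0.874 with an estimated correlation). That call ended with cyclic loess (0.169) and without any 1 of the arrays 1, 2 and 3 at 8 h and control arrays 4 and 5 (0.0531 to 0.102).

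Between 2 h and 8 h, 4749 genes differed, 2705 higher and 2044 lower at 8 h (2937 and 1415 with each array shifted to the same median, 2441 and 2648 with quantile normalization). Fos fell 33.1-fold (-5.05 ± 0.38) and Egr1 12.5-fold (-3.65 ± 0.44), within an immediate early list in which 14 of 20 genes fell and 1 rose, or 15 and 1 over the list alone (adjusted p = 4.05e-09, and adjusted p = 0.196 with an estimated correlation). Creld2 rose 15.3-fold (3.94 ± 0.33) in the unfolded protein response list, with 15 of 20 up and 2 down, also over the list alone (adjusted p = 5.38e-13, and adjusted p = 0.0539 with an estimated correlation). The cholesterol synthesis list fell in 13 of 16 genes, or 15 over the list alone (adjusted p = 1.48e-05, and adjusted p = 0.356 with an estimated correlation). In all 17 lists were called, 0 of them with an estimated correlation, where camera gave 4 at an unadjusted p under 0.05.

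At 1 d Lcn2 stood 50.1-fold above control (5.65 ± 0.80, n = 5 per group) on average, with log2 values of 8.43 on array 1 and 11.01 to 12.59 on arrays 2 to 5. Lgals3, a galectin abundant in macrophages, was 36.7-fold (5.20 ± 0.49), Nupr1, a stress-induced transcriptional regulator, 28.7-fold (4.84 ± 0.35) and Psat1 25.7-fold (4.69 ± 0.28) higher. The metallothionein gene Mt1 was 18.8-fold higher (4.23 ± 0.68), a value called uncertain because its probe set is of the type shared by near-identical copies. Upp2 fell 87.3-fold (-6.45 ± 0.53), Car3, a carbonic anhydrase of muscle, fat and liver, 23.8-fold (-4.58 ± 0.39) and Thrsp, a regulator of lipogenesis, 19.3-fold (-4.27 ± 0.57). Over all probe sets Upp2 ran from -6.86 to -1.12 and Thrsp from -4.27 to -0.42.

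Genes of differentiated hepatocytes were lower at 1 d on both sides of the lobule. Of 15 pericentral markers 12 fell and 0 rose, also over the list alone, with Slc1a2 at -3.46 ± 0.29. The cytochrome P450 gene Cyp1a2 was 7.02-fold (-2.81 ± 0.27), Glul 6.92-fold (-2.79 ± 0.18) and Cyp2e1 3.14-fold (-1.65 ± 0.27) below control. Of 14 periportal markers 12 fell (13 over the list alone). The adjusted p values were 3.99e-11 for the pericentral list (adjusted p = 0.204 with an estimated correlation) and 3.11e-08 for the periportal list (adjusted p = 0.331 with an estimated correlation). Of 21 cytochrome P450 and drug metabolism genes 17 fell and 1 rose, also over the list alone, with Cyp2c37 11.4-fold (-3.51 ± 0.51) and Cyp2c29 4.54-fold (-2.18 ± 0.19) below control (adjusted p = 8.58e-13, and adjusted p = 0.142 with an estimated correlation). Of 16 bile acid genes 14 fell and 1 rose, also over the list alone. Cyp7a1 fell 11.8-fold (-3.56 ± 0.51), Cyp8b1, the sterol hydroxylase needed for cholic acid, 8.32-fold (-3.06 ± 0.47) and Abcb11, the bile salt export pump, 4.02-fold (-2.01 ± 0.14); the export pump gene Abcc4 rose 8.66-fold (3.11 ± 0.35). The list gave an adjusted p of 6.62e-11, and adjusted p = 0.205 with an estimated correlation.

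Lipid synthesis and male-biased genes were lower at 1 d. All 16 fatty acid synthesis genes tested fell, also over the list alone, among them the desaturase gene Scd1 at -1.67 ± 0.13 and the fatty acid synthase gene Fasn at -1.51 ± 0.26 (adjusted p = 5.88e-10, and adjusted p = 0.239 with an estimated correlation). Of 16 cholesterol synthesis genes 12 fell, or 13 over the list alone (adjusted p = 5.82e-05, and adjusted p = 0.626 with an estimated correlation). All 12 male-biased liver genes fell, also over the list alone, led by the steroid dehydrogenase gene Hsd3b5 at 14.4-fold (-3.85 ± 0.42), with an adjusted p of 5.12e-11, and adjusted p = 0.178 with an estimated correlation. Of 10 female-biased liver genes 2 fell, also over the list alone, with Cyp3a44 at -0.73 ± 0.12 (adjusted p = 0.00142, and adjusted p = 0.714 with an estimated correlation; 0.0515 with the stricter filter).

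Stress and inflammatory genes were higher at 1 d. Unfolded protein response genes were up in 17 of 20, also over the list alone, with Ddit3 7.76-fold above control (2.96 ± 0.22). Heat shock genes were up in 12 of 14, also over the list alone, and ribosome biogenesis genes in 21 of 22, also over the list alone, with the nucleolin gene Ncl 3.36-fold (1.75 ± 0.14). Their adjusted p values were 5.77e-14 (adjusted p = 0.0709 with an estimated correlation), 2.12e-07 (adjusted p = 0.36 with an estimated correlation) and 2.56e-10 (adjusted p = 0.239 with an estimated correlation). Immediate early genes were up in 14 of 20 and down in 1, also over the list alone (adjusted p = 1.09e-05, and adjusted p = 0.501 with an estimated correlation). Nrf2 targets were up in 9 of 17 and down in 4 (10 and 5 over the list alone), with Srxn1 12.6-fold higher (3.66 ± 0.34). Hmox1 was not called (0.59 ± 0.27, adjusted p = 0.0614, but 0.0374 without array 3 and 0.0147 with only both groups in the fit). The Nrf2 list gave an adjusted p of 1.12e-06, and adjusted p = 0.501 with an estimated correlation. Acute phase genes were up in 16 of 22 and down in 1 (17 and 1 over the list alone), with Saa1 at 3.17 ± 0.70. Its test gave an adjusted p of 0.00419, and adjusted p = 0.755 with an estimated correlation. Array 1 at 1 d had an acute phase score, the mean difference of the list's genes from control, of -0.0511 against 1.19 to 1.78 on the other 4 arrays.

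Markers of monocyte-derived macrophages rose in 12 of 19 at 1 d (13 over the list alone), with Lgals3 and with Chil3, a chitinase-like protein of macrophages, at 15.4-fold (3.94 ± 0.32). The list gave an adjusted p of 1.99e-06, and adjusted p = 0.53 with an estimated correlation. Cytokine and chemokine genes rose in 8 of 16 and fell in 1, also over the list alone, with Ccl6 at 2.33 ± 0.42 and Ccl2, which attracts monocytes, at 0.88 ± 0.20 (adjusted p = 0.000307, and adjusted p = 0.63 with an estimated correlation). The neutrophil list was not called (adjusted p = 0.674), but 4 of its 12 genes rose and 3 fell, also over the list alone (mixed test, adjusted p = 0.00163), and the calprotectin genes S100a8 and S100a9 rose 9.51-fold (3.25 ± 0.49) and 4.29-fold (2.10 ± 0.34). Log2 values of S100a8 were 7.08 and 6.46 on arrays 1 and 2 and 8.99 to 9.45 on arrays 3 to 5. Sinusoidal endothelial markers fell in 9 of 19 and rose in 2 (10 and 2 over the list alone; adjusted p = 0.000591, and adjusted p = 0.721 with an estimated correlation). All 4 erythroid genes fell, also over the list alone, with the haem synthesis gene Alas2 at -1.05 ± 0.16 (adjusted p = 3.11e-08, and adjusted p = 0.331 with an estimated correlation). Of 6 B cell genes 2 fell, with Cd22 at -0.27 ± 0.08 (-0.25 and 0.0544 with the interquartile range as a covariate; for the list adjusted p = 0.000517, and adjusted p = 0.646 with an estimated correlation).

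In total 6623 of 13239 genes were called at 1 d, 3305 higher and 3318 lower (3718 and 2555 with each array shifted to the same median, 2872 and 3567 with quantile normalization), of which 519 and 472 changed by at least 2-fold, and 4070 with the interquartile range of each array as a covariate. Arrays 1 and 2 at 1 d stood apart from the others, with slopes of 1.18 and 0.632 of their changes on the mean change of the other arrays, against 0.91 to 1.06. Without both arrays, a choice made after seeing the data like that of the covariate, 6015 genes and 20 lists were called. Of the 24 lists called on all arrays 11 were up and 13 down, and 0 were called with an estimated correlation (9 at an unadjusted p under 0.05). The p53 target list, with 6 of 17 up and 3 down (adjusted p = 0.00982, and adjusted p = 0.818 with an estimated correlation), ended without array 2 (0.0575), without both arrays (0.108) and with quantile normalization (0.0512). The S phase list, with 5 of 20 up and 2 down (0.029, and adjusted p = 0.874 with an estimated correlation), ended without any 1 of arrays 2 and 5 and control arrays 2, 3, 4 and 5 (0.05 to 0.0826), without both arrays (0.087) and with no filter (0.0523). The circadian clock list, with 8 of 16 down, Dbp by most at -3.19 ± 0.93, and 4 up (0.029, and adjusted p = 0.864 with an estimated correlation), ended without any 1 of array 1 and control arrays 3 and 4 (0.105 to 0.142) and without both arrays (0.249). The adipose and mesothelial list, with Krt8 alone up of 5 (0.00856, and adjusted p = 0.874 with an estimated correlation), ended without array 1 (0.0802), without both arrays (0.149) and with no filter (0.776), and array 1 had an adipose list score of 1.32. The exocrine pancreas list, with 2 of 6 down (0.0033, and adjusted p = 0.818 with an estimated correlation), ended without both arrays (0.0638).

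Between 8 h and 1 d, 4194 genes differed, 2751 higher and 1443 lower at 1 d (2235 and 1854 with quantile normalization, 2312 and 1962 with cyclic loess), and 3924 without arrays 1 and 2 at 1 d. Hspa1a fell 20.1-fold (-4.33 ± 0.48) within a heat shock list in which 9 of 14 genes fell and 1 rose, also over the list alone (adjusted p = 0.000167, and adjusted p = 0.352 with an estimated correlation). Lgals3 rose 23.7-fold (4.56 ± 0.49) and Chil3 17.2-fold (4.10 ± 0.32). In all 13 of 19 monocyte-derived macrophage markers rose, also over the list alone (adjusted p = 4.79e-07, and adjusted p = 0.308 with an estimated correlation). Cyp2c37 fell 6.51-fold (-2.70 ± 0.51), and 10 of 21 cytochrome P450 genes fell, or 11 over the list alone (adjusted p = 0.000144, and adjusted p = 0.323 with an estimated correlation). In all 17 lists were called, 0 of them with an estimated correlation, where camera gave 4 at an unadjusted p under 0.05.

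**Figure D2:**
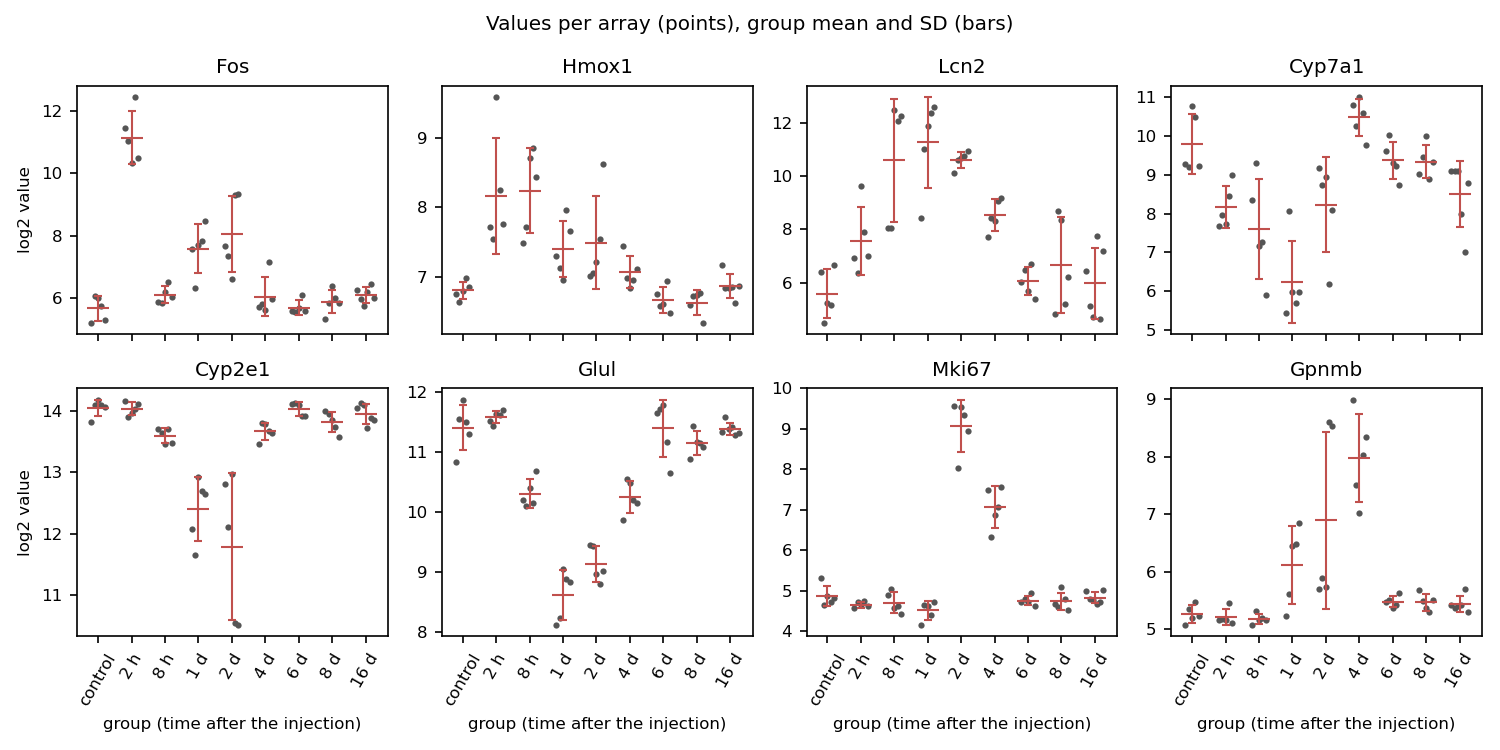
Points are the log2 values of single arrays of 8 panel genes by group, with bars for the group mean ± SD (n = 5 per group, 6 at 16 d). Fos is highest at 2 h (44.6-fold above control) and Mki67 at 2 d (18.5-fold).

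At 2 d genes of dividing cells were among those furthest above control. Birc5, which encodes the mitotic protein survivin, was 23.2-fold higher (4.54 ± 0.27, n = 5 per group) and Mki67, a marker of proliferating cells, 18.5-fold (4.21 ± 0.19), with all 5 arrays above all control arrays. Lcn2 remained 32.1-fold above control (5.00 ± 0.80) and Lgals3 17.3-fold (4.12 ± 0.49). Among the genes below control were Upp2 at 13.2-fold (-3.73 ± 0.53), Slc1a2 at 11.1-fold (-3.47 ± 0.29), Cyp2c37 at 9.91-fold (-3.31 ± 0.51), Oat at 6.90-fold (-2.79 ± 0.25) and the male-biased Cyp4a12a at 6.63-fold (-2.73 ± 0.28).

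Of 20 mitosis genes tested at 2 d 18 rose and 1 fell, also over the list alone (adjusted p = 2.55e-15, and adjusted p = 0.0709 with an estimated correlation), among them Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 14.4-fold (3.85 ± 0.24). Of 20 S phase and DNA replication genes 16 rose and 2 fell, also over the list alone (adjusted p = 8.66e-17 with fry and 0.0338 with an estimated correlation). Rrm2, the regulated subunit of ribonucleotide reductase, rose 15.4-fold (3.94 ± 0.22), Mcm5, a subunit of the replicative helicase, 14.7-fold (3.87 ± 0.26) and the cyclin gene Ccnd1 2.44-fold (1.29 ± 0.24). The mean of the B1 repeat control probe set was higher than control by 0.971 at 2 d, with all 5 arrays above all control arrays (exact permutation p = 0.00794, the smallest 5 against 5 can give, adjusted p = 0.0635). The B2 repeat probe set differed by -0.112 at 2 d (exact permutation p = 0.0238, adjusted p = 0.0634). Of 17 p53 targets 8 rose and 1 fell (8 and 2 over the list alone), with Cdkn1a at 3.13-fold (1.64 ± 0.30). Its test gave an adjusted p of 2.4e-05, and adjusted p = 0.468 with an estimated correlation.

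Markers of stellate cells and macrophages were higher at 2 d. Of 22 genes of stellate cell activation and extracellular matrix 15 rose and 1 fell, also over the list alone, with the intermediate filament gene Vim 6.04-fold (2.59 ± 0.29), the collagen gene Col3a1 4.74-fold (2.25 ± 0.30), Acta2, smooth muscle actin, 4.24-fold (2.08 ± 0.19) and Timp1, an inhibitor of matrix proteases, 2.07-fold (1.05 ± 0.18) above control. Of 12 quiescent stellate cell markers 5 rose, also over the list alone, with Dcn at 0.70 ± 0.14. Of 19 monocyte-derived macrophage markers 15 rose, also over the list alone, with Chil3 at 11.9-fold (3.57 ± 0.32) and Gpnmb, a glycoprotein of lipid-laden macrophages, at 3.08-fold (1.62 ± 0.37). The arrays at 2 d were uneven. Log2 values on arrays 1 to 3 and on arrays 4 and 5 were 5.70 to 5.89 and 8.54 to 8.61 for Gpnmb and 12.11 to 12.96 and 10.51 to 10.54 for Cyp2e1. For Ccnd1 they were 8.60 to 8.79 and 10.11 to 10.23 and for Fos 6.62 to 7.67 and 9.31 to 9.34. Scores of the monocyte-derived macrophage list were 1.15, 1.08 and 0.738 on arrays 1 to 3 and 2.50 and 2.41 on arrays 4 and 5. The 3 lists of this paragraph so far gave adjusted p = 1.71e-10 (adjusted p = 0.167 with an estimated correlation), 0.000477 (adjusted p = 0.626 with an estimated correlation) and 6.43e-08 (adjusted p = 0.301 with an estimated correlation). Cytokine and chemokine genes rose in 7 of 16 and fell in 1, with Ccl6 at 2.58 ± 0.42, and acute phase genes rose in 15 of 22, with Saa1 at 6.61-fold (2.72 ± 0.70), in both lists also over the list alone. Their adjusted p values were 0.00253 (adjusted p = 0.662 with an estimated correlation) and 0.00689 (adjusted p = 0.717 with an estimated correlation). Erythroid genes fell in 3 of 4, also over the list alone, with Alas2 at -1.11 ± 0.16 (adjusted p = 2.32e-06, and adjusted p = 0.331 with an estimated correlation).

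Hepatocyte genes were still below control at 2 d. Pericentral markers fell in 11 of 15 and rose in 1 (12 and 1 over the list alone), with Glul 4.84-fold (-2.27 ± 0.18) and Cyp2e1 4.78-fold lower (-2.26 ± 0.27). The list gave an adjusted p of 4.96e-09, and adjusted p = 0.205 with an estimated correlation. Periportal markers fell in 8 of 14 and rose in 1, also over the list alone. Its test gave an adjusted p of 0.000214, and adjusted p = 0.501 with an estimated correlation. Cytochrome P450 genes fell in 10 of 21, also over the list alone (adjusted p = 1.72e-05, and adjusted p = 0.372 with an estimated correlation). Bile acid genes fell in 10 of 16, or 12 over the list alone, with Cyp8b1 at -2.21 ± 0.47 (adjusted p = 1.09e-07, and adjusted p = 0.256 with an estimated correlation). Male-biased genes fell in 11 of 12, also over the list alone, with Elovl3 at -2.80 ± 0.67 (adjusted p = 1.91e-09, and adjusted p = 0.164 with an estimated correlation). The cholesterol synthesis list, lower at 8 h and 1 d, had a median of 0.33 at 2 d and was not called (adjusted p = 0.342), with 4 of 16 genes up and 1 down, also over the list alone.

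In total 5307 genes were called at 2 d, 2799 higher and 2508 lower (2240 and 3150 with quantile normalization), of which 415 and 148 changed by at least 2-fold, and 2504 with the interquartile range as a covariate, chosen after seeing the data. That covariate ended the calls of Cyp8b1 (-1.10, adjusted p = 0.204), Dcn (0.30, 0.239), Elovl3 (-1.99, 0.128), Nop58 (0.69, 0.126), Stab1 (0.26, 0.256), Cdkn1a (1.03, 0.0551) and Saa1 (2.54, 0.0609). Of 34 lists 24 were called, 13 up and 11 down. The immediate early list had 11 of 20 genes up, with Fos at 2.39 ± 0.38 (adjusted p = 0.000552, and adjusted p = 0.613 with an estimated correlation). The unfolded protein response list had 10 of 20 up and 1 down (0.000591, and adjusted p = 0.613 with an estimated correlation). The Nrf2 list had 7 of 17 up (0.000123, and adjusted p = 0.48 with an estimated correlation). The clock list had 6 of 16 down and 1 up (0.00239, and adjusted p = 0.613 with an estimated correlation). The B cell list had 3 of 6 down (0.00253, and adjusted p = 0.63 with an estimated correlation; 0.0985 with no filter). The exocrine pancreas list had 2 of 6 down (0.00137, and adjusted p = 0.613 with an estimated correlation). Fatty acid synthesis genes, 6 of 16 down with Scd1 at -1.20 ± 0.13 (0.0238, and adjusted p = 0.77 with an estimated correlation), ended without any 1 of arrays 3 and 5 and control arrays 2 and 4 (0.0537 to 0.0977). Ribosome biogenesis genes, 9 of 22 up with Nop58 at 1.31 ± 0.25 (0.018, and adjusted p = 0.778 with an estimated correlation), ended without any 1 of array 5 and control arrays 1 and 2 (0.0562 to 0.0738) and with quantile normalization (0.0879). Sinusoidal endothelial markers, 8 of 19 up and 2 down with Stab1 at 0.52 ± 0.12 (0.0479, and adjusted p = 0.874 with an estimated correlation), ended without any 1 of arrays 2, 4 and 5 and control arrays 1, 3, 4 and 5 (0.0544 to 0.164) and with quantile normalization (0.632), the stricter filter (0.119) and the mean of all probe sets (0.358). T and NK cell genes, 1 of 9 down (0.03, and adjusted p = 0.77 with an estimated correlation), ended without any 1 of arrays 1, 4 and 5 and control arrays 1, 2 and 3 (0.0512 to 0.0749) and with cyclic loess (0.148) and the stricter filter (0.269).

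Between 1 d and 2 d, 4283 genes differed, 2301 higher and 1982 lower at 2 d, and 4431 without arrays 1 and 2 at 1 d. Birc5 rose 30.0-fold (4.91 ± 0.27) and Mki67 23.7-fold (4.57 ± 0.19) between these times, with 18 of 20 mitosis genes and 16 of 20 S phase genes up, both also over the list alone. The mitosis list gave an adjusted p of 2.24e-16 and the S phase list 1.53e-14 with fry, and both gave 0.0299 with an estimated correlation. Cholesterol synthesis genes rose in 15 of 16 and fatty acid synthesis genes in 13 of 16 (14 over the list alone). These lists gave adjusted p = 1.88e-06 (adjusted p = 0.306 with an estimated correlation) and 3.57e-06 (adjusted p = 0.306 with an estimated correlation). Unfolded protein response genes fell in 13 of 20 (14 over the list alone), and ribosome biogenesis genes in 18 of 22 (19 over the list alone). These lists gave adjusted p = 4.03e-09 (adjusted p = 0.121 with an estimated correlation) and 1.94e-06 (adjusted p = 0.274 with an estimated correlation). In all 15 lists were called.

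At 4 d matrix and macrophage genes were among those furthest above control, and 920 genes were called. Lgals3 was 7.65-fold higher (2.94 ± 0.49, n = 5 per group), Col3a1 6.98-fold (2.80 ± 0.30), Gpnmb 6.53-fold (2.71 ± 0.37) and Smoc2, a matricellular protein, 5.52-fold (2.46 ± 0.29). Slc1a2 was 10.8-fold lower (-3.43 ± 0.29, and -0.18 with the least changed of its 3 probe sets), Oat 3.77-fold (-1.91 ± 0.25), the glucuronosyltransferase gene Ugt2b38 3.57-fold (-1.84 ± 0.43) and Cyp4a12a 3.28-fold (-1.71 ± 0.28). Of the other pericentral panel genes Glul was 2.23-fold lower (-1.16 ± 0.18, adjusted p = 1.53e-05), whereas Cyp2e1 (-0.37 ± 0.27, 0.487, but 0.0106 with only both groups in the fit) and Cyp1a2 (-0.02 ± 0.27, 0.984) were not called.

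Of 22 genes of stellate cell activation and extracellular matrix 11 rose and 0 fell against control (12 over the list alone), among them the collagen gene Col1a2 at 2.67-fold (1.42 ± 0.19). The list gave an adjusted p of 4.78e-07 with fry and 0.0361 with an estimated correlation. Acta2 (0.14 ± 0.19, adjusted p = 0.76) and Col1a1 (0.25 ± 0.12, 0.226, but 0.0363 with only both groups in the fit) were not called. Monocyte-derived macrophage markers were up in 10 of 19 (13 over the list alone), with the lysozyme gene Lyz2 at 5.04-fold (2.33 ± 0.33). Resident Kupffer cell markers were up in 5 of 12 and down in 1 (8 and 1 over the list alone). Their adjusted p values were 2.59e-05 (adjusted p = 0.106 with an estimated correlation) and 0.00296 (adjusted p = 0.301 with an estimated correlation). Quiescent stellate markers were up in 3 of 12 (7 over the list alone), with Dcn at 0.89 ± 0.14 (adjusted p = 2.98e-05, and adjusted p = 0.0927 with an estimated correlation). Sinusoidal endothelial markers were up in 7 of 19 (9 over the list alone), with Stab1 at 0.48 ± 0.12 (adjusted p = 0.000549, and adjusted p = 0.178 with an estimated correlation).

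Mitosis genes were up in 12 of 20 at 4 d (17 up and 1 down over the list alone), with Mki67 4.58-fold (2.19 ± 0.19) and Birc5 4.15-fold (2.05 ± 0.27) above control. S phase genes were up in 3 of 20 (7 over the list alone). Their adjusted p values were 1.51e-05 (adjusted p = 0.0927 with an estimated correlation) and 0.00856 (adjusted p = 0.342 with an estimated correlation). Of the fetal liver list 3 of 10 genes rose (4 over the list alone), and 3 of 17 p53 targets rose, also over the list alone. These lists gave adjusted p = 0.00365 (adjusted p = 0.317 with an estimated correlation; 0.815 with the stricter filter) and 0.00101 (adjusted p = 0.178 with an estimated correlation). Male-biased genes were still lower, with 7 of 12 down (8 over the list alone) and Cyp4a12a among them (adjusted p = 0.000364, and adjusted p = 0.167 with an estimated correlation).

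Of the 920 genes called at 4 d 628 were higher and 292 lower, and 121 and 15 changed by at least 2-fold. The count was 1622 with only both groups in the fit and 2071 with array weights. The fry test called 13 lists, 10 up and 3 down. Of these the interferon response list, with 4 of 17 genes up (8 over the list alone) and Ifit2 by most at 1.09 ± 0.18 (adjusted p = 0.0242, and adjusted p = 0.468 with an estimated correlation), ended without any 1 of arrays 2 and 3 and control array 5 (0.0506 to 0.0598) and with the stricter filter (0.0515). The clock list, down with 0 of 16 genes called, also over the list alone (adjusted p = 0.0109, and adjusted p = 0.36 with an estimated correlation), ended without control array 3 (0.0529). The erythroid list, down with 0 of 4 genes called (2 over the list alone; 0.0357, and adjusted p = 0.508 with an estimated correlation), ended without any 1 of arrays 1 and 5 and control arrays 1, 2, 3 and 4 (0.0646 to 0.121), with no filter (0.285) and with the mean of all probe sets (0.0993).

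Between 2 d and 4 d, 4139 genes differed, 1772 higher and 2367 lower at 4 d (2231 and 1810 with quantile normalization). Mcm5 fell 6.39-fold (-2.68 ± 0.26), Rrm2 5.61-fold (-2.49 ± 0.22) and Birc5 5.59-fold (-2.48 ± 0.27). Of 20 S phase genes 16 fell and 2 rose, also over the list alone (adjusted p = 3.13e-14 with fry and 0.0299 with an estimated correlation), and 18 of 20 mitosis genes fell, also over the list alone (adjusted p = 2.09e-09, and adjusted p = 0.16 with an estimated correlation). Pericentral markers rose in 11 of 15, with Cyp2e1 at 3.69-fold (1.88 ± 0.27), bile acid genes in 8 of 16, with Cyp7a1 at 4.74-fold (2.24 ± 0.51, and 1.58 at adjusted p = 0.0985 with the interquartile range as a covariate). Fatty acid synthesis genes rose in 11 of 16 (12 over the list alone), with Scd1 at 2.75-fold (1.46 ± 0.13). Their adjusted p values were 3.57e-06 (adjusted p = 0.253 with an estimated correlation), 2.03e-05 (adjusted p = 0.308 with an estimated correlation) and 0.000137 (adjusted p = 0.346 with an estimated correlation). In the stellate activation list 6 of 22 genes fell and 2 rose, also over the list alone, with Acta2 3.85-fold (-1.95 ± 0.19) and Tagln 3.07-fold (-1.62 ± 0.15) lower (adjusted p = 0.0314, and adjusted p = 0.768 with an estimated correlation; 0.0805 with quantile normalization and 0.119 with the mean of all probe sets). In all 16 lists were called, and 1604 genes with the interquartile range as a covariate, chosen after seeing the data.

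Between 4 d and 6 d, 1431 genes differed, 465 higher and 966 lower at 6 d (676 and 900 with quantile normalization). Lgals3 fell 6.22-fold (-2.64 ± 0.49), Gpnmb 5.63-fold (-2.49 ± 0.37) and Mki67 4.96-fold (-2.31 ± 0.19), while Ugt2b38 rose 6.26-fold (2.65 ± 0.43). The mitosis list fell in 14 of 20 genes and rose in 1 (18 and 1 over the list alone). The stellate activation list fell in 11 of 22 (13 over the list alone) and the monocyte-derived macrophage list in 8 of 19 (11 over the list alone). Their adjusted p values were 4.53e-06 (adjusted p = 0.149 with an estimated correlation), 8.89e-06 (adjusted p = 0.149 with an estimated correlation) and 0.000189 (adjusted p = 0.224 with an estimated correlation). Male-biased genes rose in 9 of 12, also over the list alone (adjusted p = 8.89e-06, and adjusted p = 0.121 with an estimated correlation). Fatty acid synthesis genes fell in 10 of 16 (11 over the list alone). Cholesterol synthesis genes fell in 10 of 16 (12 over the list alone). These lists gave adjusted p = 0.000147 (adjusted p = 0.217 with an estimated correlation) and 0.0041 (adjusted p = 0.338 with an estimated correlation). In all 14 lists were called, 0 of them with an estimated correlation, where camera gave 9 at an unadjusted p under 0.05. Array weights moved the count of genes to 2701.

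**Figure D3:**
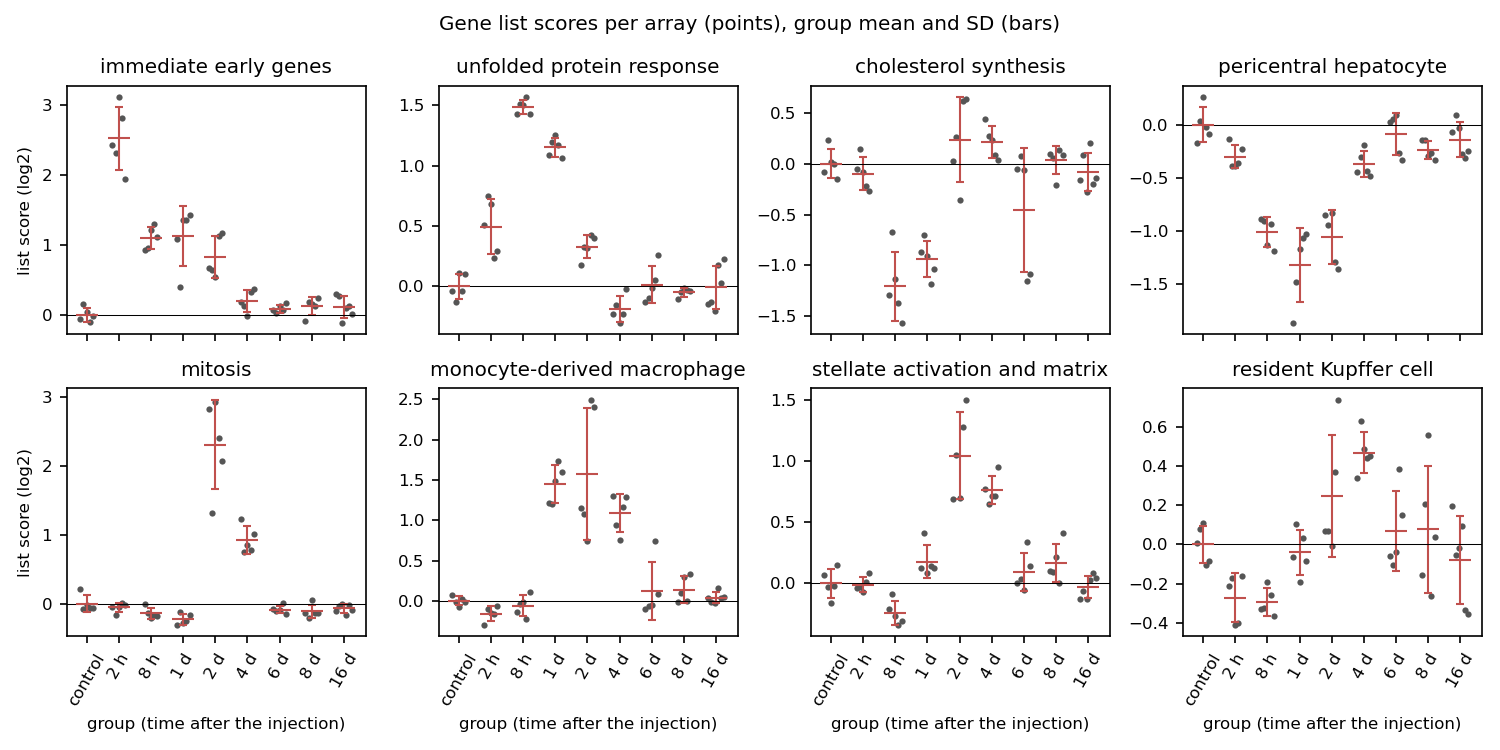
Points are single arrays, and the vertical axis is the list score, the mean over the list's genes of the log2 value minus the control mean, for 8 gene lists by group with group mean ± SD (n = 5 per group, 6 at 16 d). Immediate early genes are highest at 2 h (19 of 20 called up), unfolded protein response genes at 8 h (19 of 20) and mitosis genes at 2 d (18 of 20).

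At 6 d few genes differed from control. Zbtb7a, a transcriptional repressor, was 1.63-fold higher (0.71 ± 0.12, n = 5 per group), Ceacam1, a cell adhesion molecule, 1.62-fold (0.70 ± 0.12) and the splicing-related gene Scaf11 1.32-fold (0.40 ± 0.08), with adjusted p values of 0.00421, 0.0103 and 0.0283. The Zbtb7a and Ceacam1 calls ended with probe sets ending in _x_at or _s_at left out (0.904 and 0.821) and the Scaf11 call with the mean of all probe sets (0.925). Ceacam1 was not called without any 1 of arrays 4 and 5 and control array 1 (0.0631 to 0.0884), nor Scaf11 without any 1 of arrays 1 and 5 and control arrays 1, 2, 4 and 5 (0.0631 to 0.171). The panel genes of earlier times were close to control, with Cyp2e1 at -0.01 ± 0.27, Glul at -0.01 ± 0.18, Mki67 at -0.12 ± 0.19, Gpnmb at 0.21 ± 0.37 and Lcn2 at 0.46 ± 0.80 (adjusted p from 0.969 to 0.997). The fatty acid synthesis list was lower with a median of -0.47 and 0 of 16 genes called (9 over the list alone), at an adjusted p of 0.0256, and adjusted p = 0.178 with an estimated correlation. Its call ended without any 1 of arrays 4 and 5 and control arrays 2 and 4 (0.0602 to 0.113). The number of lists called was 2 without array 1, 2 or 3.

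These 3 genes were the only limma calls of 13239 at 6 d, with 914 at an unadjusted p under 0.05 and 0 changed by at least 2-fold. The count was 12 without array 2, 1 without array 5 or control array 1 and 6 without control array 3. The Cre and BioB hybridization spike-ins lay above their control values by 0.345 (adjusted p = 0.0212, exact permutation test) and 0.546 (0.0317). With only both groups in the fit the count was 0 (1503 at an unadjusted p under 0.05), and it was 0 with the Cre or BioB values as a covariate (693 and 1062 at an unadjusted p under 0.05), covariates chosen after seeing the data.

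At 8 d the genes below control were led by Oat, which was 2.38-fold lower (-1.25 ± 0.25, n = 5 per group, adjusted p = 0.0208), and by the phosphatase gene Lhpp (-0.77 ± 0.15, 0.0192). Those above control included Zbtb7a (0.61 ± 0.12, 0.0131), Scaf11 (0.49 ± 0.08, 0.0013) and the lipoprotein receptor gene Lsr (0.46 ± 0.08, 0.00617). The Oat call ended without any 1 of arrays 3 and 5 and control arrays 3 and 5 (0.0574 to 0.0898), and that of Lhpp without any 1 of arrays 3 and 5 and control array 5 (0.0574 to 0.0766). With the Arntl minus Dbp value of each array, the clock covariate, Oat was at -0.93 (0.255) and Lhpp at -0.59 (0.202). With the 18S covariate they were at -1.25 (0.077) and -0.73 (0.0966). Those of Zbtb7a and Lsr ended with only both groups in the fit (0.115), that of Zbtb7a also with probe sets ending in _x_at or _s_at left out (0.97), and that of Scaf11 with the mean of all probe sets (0.824). Saa1 (1.21 ± 0.70, adjusted p = 0.604), Lcn2 (1.06 ± 0.80, 0.729) and Cyp2e1 (-0.23 ± 0.27, 0.852) were not called. The circadian clock list was lower with a median of -0.27, with 0 of 16 genes called and 1 up and 4 down over the list alone (adjusted p = 0.0226, and adjusted p = 0.301 with an estimated correlation). Its call ended without any 1 of arrays 3, 4 and 5 and control arrays 3 and 4 (0.0514 to 0.0895) and with no filter (0.0601). The number of lists called was 3 without array 1 and 2 without array 2 or control array 1.

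In total limma called 19 genes at 8 d, 9 higher and 10 lower (10 and 7 with quantile normalization), with 1318 at an unadjusted p under 0.05 and 1 changed by at least 2-fold. The count was 42 without array 1, 30 without array 2, 7 without array 3, 12 without array 4 and 6 without array 5. It was 8, 9 and 11 without control arrays 3, 4 and 5. It was 0 with the Cre or BioB values as a covariate (761 and 1170 at an unadjusted p under 0.05). Both spike-ins lay above control, Cre by 0.432 (adjusted p = 0.0212, exact permutation test) and BioB by 0.715 (0.0317).

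At 16 d, the last time (n = 6 against 5), the chemokine gene Cxcl1 was 2.56-fold above control (1.35 ± 0.37, adjusted p = 0.0494) and the nuclear noncoding RNA Malat1 1.66-fold (0.73 ± 0.13, 0.00453). Ceacam1 (0.57 ± 0.12), Scaf11 (0.43 ± 0.07) and the translation factor gene Eif5b (0.40 ± 0.09) were also higher. The zinc finger gene Zfp612 was 1.68-fold lower (-0.75 ± 0.14, 0.00453) and Smim4 1.62-fold (-0.69 ± 0.10, 0.000246). The Cxcl1 call ended without any 1 of arrays 2, 4, 5 and 6 and of the 5 control arrays (0.0533 to 0.13) and with cyclic loess (0.051), the mean of all probe sets (0.0643) and several other settings, that of Malat1 without control array 5 (0.0519) and that of Eif5b without control array 4 or 5 (0.0748 and 0.122) and with the replicate block (0.0531). Ceacam1 was not called with probe sets ending in _x_at or _s_at left out (0.519), nor Scaf11 and Eif5b with the mean of all probe sets (0.781 and 0.683). Of the panel, Cyp7a1 (-1.29 ± 0.48, adjusted p = 0.152), Saa1 (1.14 ± 0.67, 0.36) and Cyp2e1 (-0.09 ± 0.26, 0.874) were not called. The fatty acid oxidation and PPAR alpha list was lower with 1 of 17 genes called, the acyl-CoA dehydrogenase gene Acadvl (-0.30 ± 0.08, 0.0569 to 0.177 without any 1 of arrays 2 to 6 and control arrays 2 to 5), or 2 over the list alone (adjusted p = 0.0326, and adjusted p = 0.501 with an estimated correlation). The B cell list was higher with a median of 0.16, 0 of 6 genes called and 1 over the list alone (adjusted p = 0.00884, and adjusted p = 0.204 with an estimated correlation; 0.0575 with no filter). The fatty acid oxidation call ended without any 1 of arrays 4, 5 and 6 and control arrays 2, 4 and 5 (0.0537 to 0.143), with the replicate block (0.0986), quantile normalization (0.151), cyclic loess (0.162) and the mean of all probe sets (0.0611). Without array 1 the number of lists called was 4.

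In total 200 genes were called at 16 d, 55 higher and 145 lower, and 4 of them by at least 2-fold. The split was 43 and 250 with each array shifted to the same median, 90 and 77 with quantile normalization and 43 and 48 with cyclic loess. The count was 331 without array 1, 108, 110, 39 and 86 without arrays 3, 4, 5 and 6, and 67 and 8 without control arrays 4 and 5. It was 50 with the replicate block, 1010 with array weights, 85 with the mean of all probe sets, 127 with the clock covariate, 80 with the 18S covariate, 4 with the interquartile range as a covariate and 0 with the Cre spike-in (1531 at an unadjusted p under 0.05), where the covariates were chosen after seeing the data. At this time the interquartile range differed from control by -0.0752 (adjusted p = 0.0212) and the Cre value by 0.337 (0.0173, exact permutation tests).

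Between 6 d and 8 d limma called 1 gene, Lsr, which rose by 0.49 ± 0.08 (adjusted p = 0.00653) and was chosen here after its values were seen (0.0591 without array 4 at 6 d, 0.105 without array 5 at 8 d, 0.131 with the mean of all probe sets, 0.113 with only both groups in the fit), with 949 at an unadjusted p under 0.05. Between 8 d and 16 d it called 0, with 1404. The fatty acid synthesis list had a median of 0.40 and the cholesterol synthesis list of 0.46 from 6 d to 8 d, each with 0 of 16 genes called and 7 and 9 over the list alone. They were called with adjusted p = 0.0364 (adjusted p = 0.217 with an estimated correlation) and 0.0427 (adjusted p = 0.224 with an estimated correlation; 0.0602 with the mean of all probe sets). From 8 d to 16 d the B cell list was called upward with a median of 0.10 and 0 of 6 genes called (adjusted p = 0.0434, and adjusted p = 0.284 with an estimated correlation), and this ended with the replicate block (0.0636), cyclic loess (0.0552), no filter (0.256) and the mean of all probe sets (0.0766). The count from 6 d to 8 d was 7 without array 2 at 6 d, 0 without array 4 at 6 d or array 5 at 8 d (829 and 800 at an unadjusted p under 0.05) and 3 without array 4 at 8 d. The count from 8 d to 16 d was 5 without array 2 at 16 d.

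Calls shared between times were counted because the comparisons use the same 5 control arrays. At 2 h and 8 h, 2160 genes were called in the same direction and 170 in opposite directions. Independent lists of those sizes would share 789, splitting the controls between the times gave a median of 1232.5 (902 to 1440 over 20 splits), and unchanged simulated groups shared 0. At 1 d and 2 d, 3551 genes were called alike and 119 oppositely, beside 1327 for independent lists, 2210.5 (1942 to 2314) with split controls and 0 in simulation. At 1 d and 16 d, 47 genes were called alike and 55 oppositely, beside 50.07 for independent lists, 2 (0 to 27) with split controls and a simulated mean of 1.26 (highest 126 of 100 draws). That overlap was 16 without control array 4 and 3 without control array 5. The list of cholangiocyte and ductular genes, which mark bile duct cells, was not called at any time (7 genes tested, adjusted p from 0.172 to 0.996), and 2 of its genes were called up at 2 d (1 over the list alone).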

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

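All tests of explanations and of other splits in this part were chosen after the results were seen. Of 306 groups of list scores, 21 held an array far from the others, where about 1 in 20 (15.3) would by chance. Array 1 at 1 d gave 5 of them, with scores of -1.66 for cytochrome P450 genes, -1.901 for bile acid genes, -0.3552 for B cell genes, -0.0922 for cholangiocyte genes and 1.317 for adipose and mesothelial genes. Array 4 at 6 d gave 3, with 0.2632 for cytokines, 0.7465 for monocyte-derived macrophages and 0.2637 for cholangiocytes. Control array 1 stood apart for S phase (0.1716) and mitosis (0.2163), and array 3 at 8 d for cholesterol synthesis (-0.2077) and mitosis (0.0534). At 8 h array 4 stood apart for cytochrome P450 genes (-0.3234), array 2 for quiescent stellate cells (-0.1203) and array 1 for cholangiocytes (-0.0084). The others were array 2 at 1 d for stellate activation (0.4116), array 3 at 2 d for T and NK cells (-0.0719), array 1 at 4 d for fatty acid synthesis (0.7534), array 5 at 6 d for interferon (-0.2205), and for B cells array 4 at 8 d (-0.001) and array 1 at 16 d (0.0501).

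Lists called in opposite directions at different times are named here with the adjusted p of the difference over 5 lists. They and their times were picked by those calls, so that p adds no evidence, and none of the calls held with an estimated correlation. They were quiescent stellate (medians 0.27 at 4 d and -0.10 at 8 h, adjusted p = 4.27e-10), Kupffer (0.55 and -0.42, 5.42e-08) and endothelial markers (0.19 and -0.30, 3.83e-11) at the same times, B cell genes (0.16 at 16 d and -0.20 at 1 d, 3.06e-09) and exocrine pancreas genes (0.13 at 2 h and -0.21 at 2 d, 3.06e-09). Among probe sets outside the gene comparisons, 375 of 606 that name several genes and 1240 of 3144 with no listed gene were called by limma at 1 d.

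Array 1 differed from the others at 1 d. Its Gapdh 3 prime minus 5 prime value of 0.111 lay within their 0.095 to 0.309, which argues against RNA quality. Its r across genes was 0.957 with the mean of the others and 0.939 with 8 h, the next closest group. That argues against an array of another group. The slope (1.18) and the P450 and bile acid scores go with a larger response. The acute phase score (-0.0511 against 1.19 to 1.78) does not, so this stays open. No biological explanation was tested.

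The 200 genes called at 16 d all kept their sign with quantile normalization, but 116 stayed called (median size 0.325 against 0.37), so the spread of values and spike-in level of arrays cannot be told apart from the group. With the interquartile range covariate 3 did (median 0.242, SE 0.0964). With the clock covariate 105 stayed called, all signs held and the median was 0.356 (SE 0.089). The size moved little but many calls ended, so time of day as this covariate tracks it was not decided. With the Cre covariate 0 did (limma, 1531 at an unadjusted p under 0.05), with signs kept, a median of 0.323 and the SE up from 0.0891 to 0.112. Of 200 genes ranked first at 16 d in each control split, 83.8% (73 to 88.5 over 20 splits) kept their sign at 8 d with the other controls and 76% (51.5 to 85.5) at 6 d. Controls apart from all late arrays could give this. A lasting treatment effect stays open and was not separated from these.

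The circadian clock list was lower at 8 d, where Dbp was 10.31 and 10.10 on arrays 1 and 2, 5.07 to 6.12 on arrays 3 to 5 and 8.34 to 10.62 in controls. Of other clock genes 92.9% (13 of 14) had the sign of their relation to Arntl minus Dbp within other groups, as another time of day would give. Of 16 clock genes 4 lay above control, which argues against an array-wide level. The arrays did not move together, and a treatment effect stays open.

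Splits of the same arrays into other groups were drawn 100 times per comparison, the real one included. For genes, only the real split reached its count at 2 h (3486, highest other 1321), 8 h (5549, 2969), 1 d (6623, 4624), 2 d (5307, 2431) and 4 d (920, 112), for the steps from 2 h to 6 d (4749, 4194, 4283, 4139 and 1431 against 3721, 2417, 3508, 1779 and 235) and for the F-test (11042, 227). Chance was excluded there. It was not excluded at 6 d (3, highest other 7, 6 splits as large), 8 d (19, 43, 2) and 16 d (200, 270, 2). Nor was it from 6 d to 8 d (1, 84, 9) and from 8 d to 16 d (0, 257, 100). The splits with the most genes at 8 d, from 6 d to 8 d and from 8 d to 16 d had the largest Arntl minus Dbp difference of all splits possible (5.206, 6.297 and 5.137), which points to a structure of the samples. For lists chance was taken as excluded by the same line from 2 h to 4 d (9, 19, 24, 24 and 13 lists against 8, 14, 19, 18 and 7) and for the steps from 2 h to 1 d and 2 d to 6 d (17, 17, 16 and 14 against 13, 10, 13 and 7). It was not excluded at 6 d (1, highest other 3, 31 splits), 8 d (1, 4, 33), 16 d (2, 5, 11), from 1 d to 2 d (15, 18, 2), from 6 d to 8 d (2, 3, 20) and from 8 d to 16 d (1, 5, 24).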

How the results depend on the processing

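Covariate fits and the fit without arrays 1 and 2 at 1 d were chosen after seeing the data. Counts of genes stayed within 1.5 times with every array shifted to the same median, no filter, the stricter filter, trend and robust variances and the Gapdh covariate. The counts that moved follow, and the cause was not tested except where fewer samples or a fold threshold set it. Quantile normalization gave 3 genes from 6 d to 8 d, and cyclic loess 2 there and 91 at 16 d. The mean of all probe sets gave 1 at 6 d, 85 at 16 d and 0 from 6 d to 8 d (785 at an unadjusted p under 0.05), and leaving out _x_at and _s_at probe sets 0 at 6 d (886). With only both groups in the fit the counts were 1622 at 4 d, 0 at 6 d (1503), 11 at 8 d, 2746 from 8 h to 1 d, 2387 from 1 d to 2 d and 0 from 6 d to 8 d (1223). Array weights gave 2071 at 4 d, 14 at 6 d, 90 at 8 d, 1010 at 16 d, 2701 from 4 d to 6 d, 7 from 6 d to 8 d and 8 from 8 d to 16 d. Adjusting over all contrasts gave 230, 443 and 922 at 6 d, 8 d and 16 d and 236 and 418 for the last steps. A fold of at least 2 left 194, 873, 991, 563, 136, 0, 1 and 4 genes from 2 h to 16 d and 520, 354, 490, 335, 159 and 0 for the steps to 8 d. Treat against a fold of 1.5 left 97, 844, 1011, 439, 48, 0, 0 and 0 (7, 7 and 6 at an unadjusted p under 0.05 for the last) and 415, 202, 346, 172, 62 and 0 (5). The clock covariate gave 5 at 8 d and 127 at 16 d, the interquartile range 4070 at 1 d, 2504 at 2 d, 4 at 16 d and 1604 from 2 d to 4 d. The Cre covariate gave 0 at 6 d, 8 d and 16 d (693, 761 and 1531), BioB 0 at 6 d and 8 d (1062 and 1170), and 18S 5, 8 and 80 at 6 d, 8 d and 16 d and 1 from 8 d to 16 d. Camera with the preset correlation called 5, 14, 4, 5 and 4 lists at 2 h, 1 d, 6 d, 8 d and 16 d and 11, 8, 7 and 7 from 2 h to 8 h, 8 h to 1 d, 6 d to 8 d and 8 d to 16 d. With an estimated correlation it called 2, 1, 0, 1, 1, 0, 0 and 0 lists from 2 h to 16 d (4, 4, 9, 8, 9, 3, 1 and 1 at an unadjusted p under 0.05) and 0, 0, 2, 1, 0, 0 and 0 for the steps (4, 4, 8, 5, 9, 2 and 3). It ended 167 list calls, and the 343 results it kept were mostly not calls. The number of lists was 1 at 16 d and 2 from 8 d to 16 d with quantile normalization, 2 at 6 d, 1 at 16 d and 0 from 8 d to 16 d with cyclic loess, 2, 0 and 1 at 6 d, 8 d and 16 d and 0 from 8 d to 16 d with no filter, 1 at 16 d with the stricter filter, and 2, 2 and 1 at 6 d, 8 d and 16 d, 1 from 6 d to 8 d and 0 from 8 d to 16 d with the mean of all probe sets. Overlaps were 112, 301 and 3 with a fold of at least 2 and 1232.5, 2210.5 and 2 with split controls. The largest-change times stayed within 1.5 times in both settings run.

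Of 15 comparisons 0 had every same-numbered correlation above 0.1 (-0.274 to 0.336). This rule misses runs of arrays (Dbp at 8 d). With the replicate block 50 genes were called at 16 d, 2 lists at 6 d and 1 at 16 d, and other counts stayed within 1.5 times. The block ended 4 list calls and made 5. Without each array in turn the counts were 2610 to 3684, 4969 to 5494, 5878 to 6786, 4522 to 5341, 671 to 919, 1 to 12, 6 to 42 and 8 to 331 from 2 h to 16 d. For the steps they were 3903 to 4960, 3607 to 4116, 3770 to 4704, 3391 to 4251, 1006 to 1370, 0 to 7 and 0 to 5, and for the F-test 10845 to 11112. Lists numbered 7 to 9, 17 to 20, 22 to 25, 20 to 23, 11 to 13, 0 to 2, 0 to 3 and 1 to 4, and overlaps 1789 to 1957, 3066 to 3428 and 3 to 48.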

Other observations

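These genes were put together after their values were seen. At 4 d pericentral genes differed in how far they lay from control. Slc1a2 (-3.43 ± 0.29), Oat (-1.91 ± 0.25) and Glul (-1.16 ± 0.18) were still called below control (limma), while Cyp2e1 (-0.37 ± 0.27, adjusted p = 0.487) and Cyp1a2 (-0.02 ± 0.27, 0.984) were not, and whether they differ from each other was not tested. At 8 d Oat was at -1.25 ± 0.25 (0.0208, and -0.93 and 0.255 with the clock covariate) and Slc1a2 at -1.02 ± 0.29 (0.15).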
